A study of Homo sapiens with 18 samples.

How the data were processed

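Nascent transcription was measured in 18 human livers, in a study of people with obesity, by leChRO-seq. In this variant of run-on sequencing RNA polymerases still bound to chromatin extend their transcripts with labelled nucleotides, so that reads mark where transcription was under way. The titles place 6 livers in a steatohepatitis-resistant group (NR) and 8 in a steatohepatitis-prone group (NP), and 4 livers met neither definition, per the submitters. The titles and status fields of these 4 name no group, although the deposited count columns carry NR in the names of 2 and NP in those of the other 2. They entered no fit and no test. Each library came from a separate liver, per the labels, so the spread within a group is a spread between people. Replicate numbers only name libraries, in the order of deposition, and pair nothing.

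The authors deposited raw read counts per gene body and raw read counts per transcriptional regulatory element (TRE), an element called by dREG from the run-on signal and typed by the authors as enhancer or promoter. Per the submitters' processing notes, FastQC, cutadapt 1.16, BWA and build hg38 were used. The counting tool, its strand rule, the gene annotation version, the aligner settings and how elements were called across libraries are not given in the sources used here. A gene and an antisense or overlapping partner can therefore share counts, near-identical genes such as members of the GSTA and SAA families can share reads, and an element inside a gene body can hold reads of polymerase passing through that gene. The handling of duplicate reads is also not given in the sources used here, so counts need not be independent molecules.

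The authors deposited counts for 24798 genes and for 136863 elements. Genes on chromosome Y, XIST and TSIX, and the elements over them, were left out of every table (292 genes and 12 elements). All sample columns of both tables were matched to a sample by name. The column names also carry a prefix, CC or CG, and each occurs in both groups. The prefix entered no fit and no test. Of the genes kept, 21444 matched a RefSeq symbol of GRCh38.p14, 472 an older symbol, and 2590 had no match and kept the name in the file. The element coordinates fitted that annotation: 76.1% of promoter-type and 12.9% of enhancer-type elements lay within 1000 bp of an end of an annotated gene. The annotation table gave gene spans without strand or exons, so neither transcription start sites nor exon positions could be used. Either end of a gene took the place of the start site that had been planned.

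Gene-body totals ran from 1351105 to 25659963 counts in NR and from 2753328 to 22239538 in NP. The groups differed in log10 total by 0.13 (two-sided exact permutation p = 0.568 over 3003 arrangements). None of the 153 pairs of libraries held identical values, and log-scale correlations between libraries were 0.924 to 0.99. The simulated data below show the recovery that this depth would allow if features varied independently.

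The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the counts as deposited, with TMM normalization, the default expression filter by group, robust dispersion, no covariate, and a two-sided Benjamini-Hochberg adjusted p under 0.05. Fold changes are NR minus NP on the log2 scale. Each standard error was calculated back as the size of the fold change divided by the square root of the test's F statistic, so it is approximate. Log2 CPM values used a prior count of 2. The filter left 16580 genes and 61473 elements. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, then with the estimated correlation, with fry, and by exact permutation of the mean centred log2 CPM of the members in each library, called the list score. Of 32 lists, 31 had at least 3 members tested and the erythroid list had 0.

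The gene lists, the test designs, the rules for naming genes and elements and the first group of alternatives below were fixed before the data were examined. The rule for genes took the 10 genes higher and the 10 lower in NR with the largest change among those past the threshold and with a mean log2 CPM of at least 0, filled by the smallest unadjusted p where fewer passed, plus the 3 members with the smallest p of each list called by camera and any list gene that passed. No gene or element passed, so all of the former were chosen by unadjusted p. Some genes that the rule takes are not reported here, and no other gene took their place. The rule for elements took the 5 with the smallest p in each direction, plus the 5 genes with most called elements nearby, of which there were none. The planned Fisher's exact test of distal against proximal elements had no called element to use, so it was run at an unadjusted p under 0.01, and the score of each library was added after the data were seen.

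The first group of alternatives were DESeq2 1.42.0, DESeq2's size factors within edgeR, total counts in place of TMM, no count filter, at least 1 CPM in 6 libraries, limma voom, flow cell as a fixed or random block, flow cells 1 and 4 alone or together, the group given by the subject status field, leaving out the 2 libraries whose fields disagree, leaving out each library, gene-body library sizes for the elements, and other distances and windows. Alternatives added after the data were seen left out the 2 libraries with 1351105 and 2753328 gene-body counts, thinned every library to the shallowest, used unadjusted p thresholds, the authors' element types, exact permutation of list scores and elements near list genes, joined elements into regions, and left out each library in the list tests. On the real counts, DESeq2 and the fit with no count filter took every feature with at least 1 count, so they covered more features than the main test. Flow cell 2 held only NR and flow cell 3 only NP among the grouped livers, so within-batch comparisons rest on flow cells 1 and 4.

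The tests were checked on simulated data drawn from the real means, dispersions and library sizes with 200 changed features. In the genes, edgeR recovered 44% of 2-fold and 87% of 4-fold changes, with 7 false among 138 calls, and DESeq2 recovered 62% and 92%, with 29 false among 183 calls. In the elements, edgeR recovered 5% of 2-fold and 52% of 4-fold changes, with 0 false among 57 calls, and DESeq2 14% and 62%, with 20 false among 96 calls. A first requirement that edgeR recover more than 60% of 4-fold changes in the elements was not met and was replaced. Recovery of 4-fold changes in the elements was 20.9% under a mean of 30 counts, 63.9% from 30 to 99 and 95.2% at 100 or more, and 52.5% of the tested elements lay under 30. The requirement was then set on features with a mean of 100 counts or more, where genes reached 95.6%. In simulated lists, camera called the 1 changed list and 0 of the others. In all of these simulations features were independent, unlike real ones, so the rates need not hold in the livers.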

Results

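The livers of people with obesity were compared by their resistance to steatohepatitis, asking which genes and regulatory elements are transcribed differently in resistant (NR, n = 6) and prone (NP, n = 8) livers. Gene-body totals were 1351105 to 25659963 counts in NR, 2753328 to 22239538 in NP and 9362973 to 29157770 in the 4 livers of neither group. In the elements the totals were 447489 to 8959056 counts in NR and 766970 to 8876161 in NP. For 2 libraries, NR replicate 1 and NP replicate 1 by title, both in flow cell 1, the subject status field named the other group. The names of their count columns carry the group of the title. The titles were used, and both other choices were run.

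The genes with the smallest p between NR and NP included SH3BGR and SH3RF2 on the higher side. SH3BGR (ENSG00000185437.13, chromosome 21, 39445865 to 39515506, hg38) had 11.3 ± 1.52 CPM in NR (SD, n = 6) and 4.73 ± 1.22 CPM in NP (n = 8), a log2 difference of 1.25 ± 0.21 (SE). SH3RF2 differed by 1.92 ± 0.33. LPA, which encodes apolipoprotein(a), had 143 ± 22.2 CPM in NR and 71.8 ± 23.2 CPM in NP, a log2 difference of 0.99 ± 0.20. On the lower side, PTMA, the gene of prothymosin alpha, at 231708525 to 231713551 on chromosome 2, differed by -0.95 ± 0.19, CRIP1 by -1.88 ± 0.41, B3GNT5, a glycosyltransferase gene, by -1.88 ± 0.41, and CD37, a leukocyte tetraspanin gene, by -0.92 ± 0.21. Every NR library lay on the NR side of the NP mean for these genes.

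None of these genes passed in edgeR, while DESeq2 called SH3BGR, SH3RF2, LPA, PTMA, CRIP1, B3GNT5 and CD37. edgeR called 0 of 16580 genes, with a smallest adjusted p of 0.114. At an unadjusted p under 0.05 there were 1286 genes higher and 1558 lower in NR, 2844 in all against 829 expected by chance. DESeq2 called 137 higher and 137 lower, and limma voom called 0. Others among the genes of smallest p on the higher side were SNX31 (1.92), PCOLCE2 (1.78), RNLS (0.67), TTC6 (0.64) and GBA3 (1.56), as log2 differences, and TRPC5 (2.23-fold). On the lower side they were EVI2A (-1.39), GNB2 (-0.89), DEGS1 (-0.80) and C4orf51 (-1.13), as log2 differences, and ORAI2 (2.01-fold). NP replicate 6 stood apart from the other NP libraries for GBA3, RNLS, B3GNT5 and GNB2, and NR replicate 1 and NP replicate 5 stood apart in their groups for SNX31. With the status field as the group edgeR called 5 genes, and without the 2 libraries in dispute 9, all higher in NR. PCOLCE2, GBA3, NUCB2 and CYP2C19 were called both times, the last pair named here after their values were seen. Without NR replicate 1, a library in dispute, edgeR called 23 genes higher and 8 lower. Without NR replicate 5 the count at an unadjusted p under 0.05 was 1846, and with flow cell as a block it was 1663.

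Immediate early genes, which are transcribed within minutes of a stimulus, were lower in NR in all 27 of 27 measured members, with a median log2 difference of -1.23. ZFP36, which encodes an mRNA-decay factor, differed by -1.31 ± 0.30 and BTG2 by -1.72 ± 0.49. JUNB, an AP-1 subunit gene, had 44.0 ± 25.1 CPM in NR and 141 ± 82.1 CPM in NP (-1.68 ± 0.48). Neutrophil markers were lower in 11 of 11 members, with a median of -1.57. S100A8, which encodes a calprotectin subunit, had 0.491 ± 0.300 CPM in NR and 3.28 ± 3.33 CPM in NP (-2.79 ± 0.65). The chemokine receptor gene CXCR1 had 0.734 ± 0.860 CPM in NR and 6.38 ± 7.42 CPM in NP (-2.86 ± 0.77), and MNDA differed by -1.38 ± 0.37. S100A8 and CXCR1 were near the floor in NR, so the size of their differences is uncertain. Inflammatory and NF-kB genes were lower in 24 of 25 members, with a median of -0.88, among them the chemokine genes CCL20 (-2.65 ± 0.74) and CXCL1 (-1.60 ± 0.47) and the cytokine gene IL1B (-1.79 ± 0.57).

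Camera called these 3 lists lower at its preset correlation, with adjusted p of 6.19e-13 for the immediate early list, 2.3e-08 for the neutrophil list and 8.34e-08 for the NF-kB list. Each had an adjusted p = 0.311 with an estimated correlation. Over all genes tested by edgeR 0 members passed in any of the 3 lists, while DESeq2 called 3 immediate early, 7 neutrophil and 3 NF-kB members lower. When adjusted over the list alone, 21 immediate early, 11 neutrophil and 9 NF-kB members passed. Permuting the list scores over all 3003 arrangements gave two-sided exact p of 0.025, 0.00966 and 0.0173 (adjusted over 31 lists, 0.0994 for each). With flow cell as a block the medians were -1.63, -2.29 and -1.16. Permuting within flow cells gave an exact p of 0.0667 for the immediate early list, of 0.133 for the NF-kB list and of 0.0333 for the neutrophil list, the smallest that the 30 arrangements allow. Within flow cell 1 (1 NR, 2 NP) the medians were -0.52, -0.85 and -0.05, and within flow cell 4 (2 NR, 3 NP) -2.22, -4.32 and -1.98. Values within flow cell 1 here and below rest on disputed group labels. The immediate early median was -0.64 with the status field as the group.

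**Figure D1:**
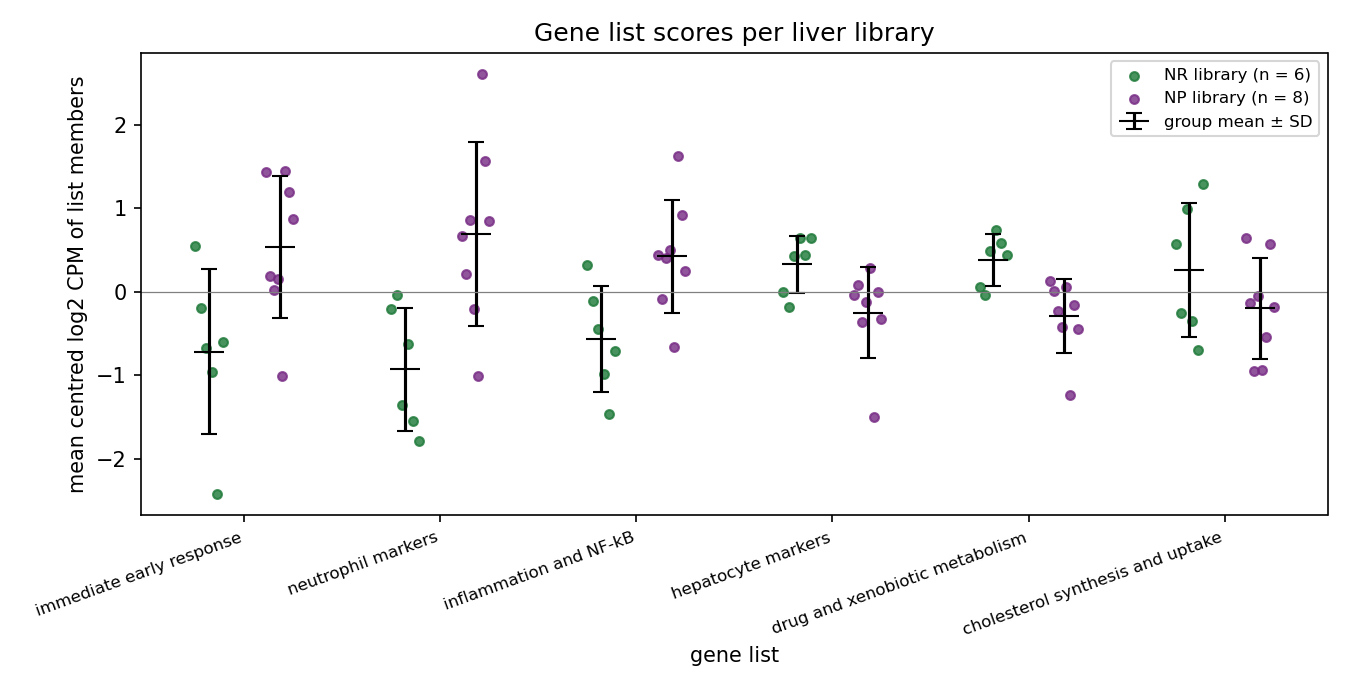
Each point is the mean centred log2 CPM of a list's members in 1 library, for 6 gene lists on the horizontal axis, with NR in green (n = 6) and NP in purple (n = 8) and bars for the group mean ± SD. The immediate early scores averaged -0.72 in NR and 0.54 in NP and the neutrophil scores -0.93 and 0.70, and the ranges of the groups overlapped in every list shown.

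Acute phase genes were lower in NR in 24 of 27 members, with a median of -0.49. SAA2 and SAA1, the genes of inducible serum amyloid A, differed by -3.82 ± 0.99 and -3.69 ± 1.03, although the NP values were spread widely (61.5 ± 87.1 CPM for SAA2, n = 8). SOCS3, a feedback inhibitor of cytokine signalling, differed by -2.12 ± 0.66. Extracellular matrix and fibrosis genes were lower in 27 of 34 members, with a median of -0.33, including VCAN (-1.70 ± 0.50), the collagen IV gene COL4A2 (-0.85 ± 0.25) and TGFB3 (-1.26 ± 0.42), for which NP replicate 6 stood apart. YAP, Notch and regeneration genes were lower in 19 of 23 members, with a median of -0.36, led by AMOTL2 (-0.75 ± 0.19), HES1 (-1.38 ± 0.38) and LATS2 (-0.51 ± 0.16). Heat shock genes were lower in 14 of 16 members, with a median of -0.40, among them the chaperone genes HSPD1 (-0.64 ± 0.21), BAG3 (-1.19 ± 0.40) and HSP90AA1 (-0.57 ± 0.27).

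Camera called these 4 lists lower at its preset correlation. The acute phase list had an adjusted p = 0.689 with an estimated correlation, the matrix list and the YAP list 0.311, also as an adjusted p with an estimated correlation, and the heat shock list an adjusted p = 0.632 with an estimated correlation. The YAP list was the only list called by fry (adjusted p = 0.0452). When adjusted over the list alone, 4 acute phase, 3 YAP, 0 matrix and 0 heat shock members passed in edgeR, and over all genes tested 0 in each list, while DESeq2 called 2 acute phase, 2 YAP, 1 matrix and 0 heat shock members lower. The acute phase call ended without NP replicate 2, NR replicate 2 or NP replicate 6, with medians of -0.35, -0.42 and -0.24. The heat shock median was -0.23 without NR replicate 5 and -0.70 without NR replicate 2. The acute phase, matrix, YAP and heat shock medians with flow cell as a block were -0.69, -0.34, -0.35 and -0.65. Within flow cell 1 they were -0.52, -0.04, -0.18 and 0.03, and within flow cell 4 -0.59, -0.46, -0.46 and -1.14.

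Hepatocyte markers were higher in NR in 18 of 20 members, with a median of 0.43, and TF, the transferrin gene, had 1101 ± 764 CPM in NR and 321 ± 145 CPM in NP (1.78 ± 0.49). F2, the prothrombin gene, differed by 0.70 ± 0.24. NP replicate 6 stood apart for TF and in hepatocyte and drug scores, at -1.49 and -1.24, and without it these medians were 0.31 and 0.41. The drug median was 0.35 without NR replicate 1, and the pericentral median 0.37 without NR replicate 5. Drug and xenobiotic metabolism genes were higher in 21 of 29 members, with a median of 0.56, among them CYP1A2 (2.51 ± 0.63), the glutathione transferase gene GSTA2 (2.93 ± 0.75) and NR1I2 (1.37 ± 0.35), which encodes the pregnane X receptor. Bile acid genes were higher in 18 of 21 members, with a median of 0.47, among them CYP8B1, the sterol 12-hydroxylase gene (1.01 ± 0.24), AKR1D1 (1.46 ± 0.42) and the uptake transporter gene SLCO1B1 (0.73 ± 0.27). Pericentral genes were higher in 15 of 19 members, with a median of 0.57, including RHBG (2.11 ± 0.89) and SLC13A3 (0.57 ± 0.23).

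Fatty acid oxidation genes were higher in NR in 28 of 33 members, with a median of 0.40, among them CPT2 (0.70 ± 0.23), ACAA2 (0.67 ± 0.22) and ACADL (0.99 ± 0.37). Cholesterol synthesis and uptake genes were higher in 25 of 26 members, with a median of 0.58, including SC5D (0.82 ± 0.26), NSDHL (0.80 ± 0.29) and EBP (0.84 ± 0.35). De novo lipogenesis genes were higher in 16 of 23 members, with a median of 0.29, led by GPAM (1.04 ± 0.29), ACACB (1.03 ± 0.30) and the pyruvate kinase gene PKLR (2.24-fold). Lipoprotein secretion genes were higher in 16 of 23 members, with a median of 0.30, led by LPA, TM6SF2 (1.47 ± 0.46) and APOH (0.69 ± 0.28). NP replicate 6 stood apart for APOH and in the lipoprotein score, at -0.96, and NR replicate 4 in the fatty acid score, at 0.53.

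All 8 of these lists were called higher by camera at its preset correlation. Members that also stand in other lists numbered 8 of 20 hepatocyte, 6 of 29 drug, 6 of 19 pericentral and 3 of 23 lipoprotein genes. They numbered 1 of 23 for bile acid, 1 of 23 for lipogenesis and 0 for fatty acid oxidation and cholesterol, so the calls are not all independent. With an estimated correlation the adjusted p was 0.311 for the drug and bile acid lists, 0.46 for hepatocyte markers, 0.568 for fatty acid oxidation, 0.632 for the pericentral and lipoprotein lists and 0.674 for the cholesterol and lipogenesis lists. When adjusted over the list alone, 5 drug, 4 hepatocyte, 2 bile acid, 2 lipogenesis, 1 pericentral and 1 lipoprotein members passed in edgeR, with 0 for fatty acid oxidation and cholesterol, and over all genes tested 0 passed in any list. DESeq2 called 4 drug, 2 hepatocyte, 2 bile acid, 1 pericentral, 1 lipogenesis and 1 lipoprotein members higher and 0 for fatty acid oxidation and cholesterol. With flow cell as a block the hepatocyte, drug, bile acid, pericentral, fatty acid, lipoprotein, cholesterol and lipogenesis medians were 0.55, 0.56, 0.49, 0.49, 0.39, 0.37, 0.56 and 0.36. Within flow cell 1 the medians of the hepatocyte, drug, bile acid, pericentral, fatty acid and lipoprotein lists were -0.11, -0.07, -0.07, -0.45, -0.11 and -0.17, and within flow cell 4 they were 0.95, 0.66, 0.54, 0.89, 0.51 and 0.69. The cholesterol and lipogenesis medians were 0.31 and 0.25 in flow cell 1 and 0.65 and 0.59 in flow cell 4. Without the 2 shallowest libraries the cholesterol, lipogenesis and lipoprotein medians were 0.31, 0.14 and 0.15 and camera no longer called them. The same 3 calls ended without NR replicate 6 alone (0.32, 0.17 and 0.11), the lipogenesis call without NR replicate 1 or 3 or NP replicate 3 or 5 (0.22, 0.26, 0.24 and 0.25), and the lipoprotein call without NR replicate 4 or NP replicate 4 or 8 (0.21, 0.26 and 0.27).

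**Figure D2:**
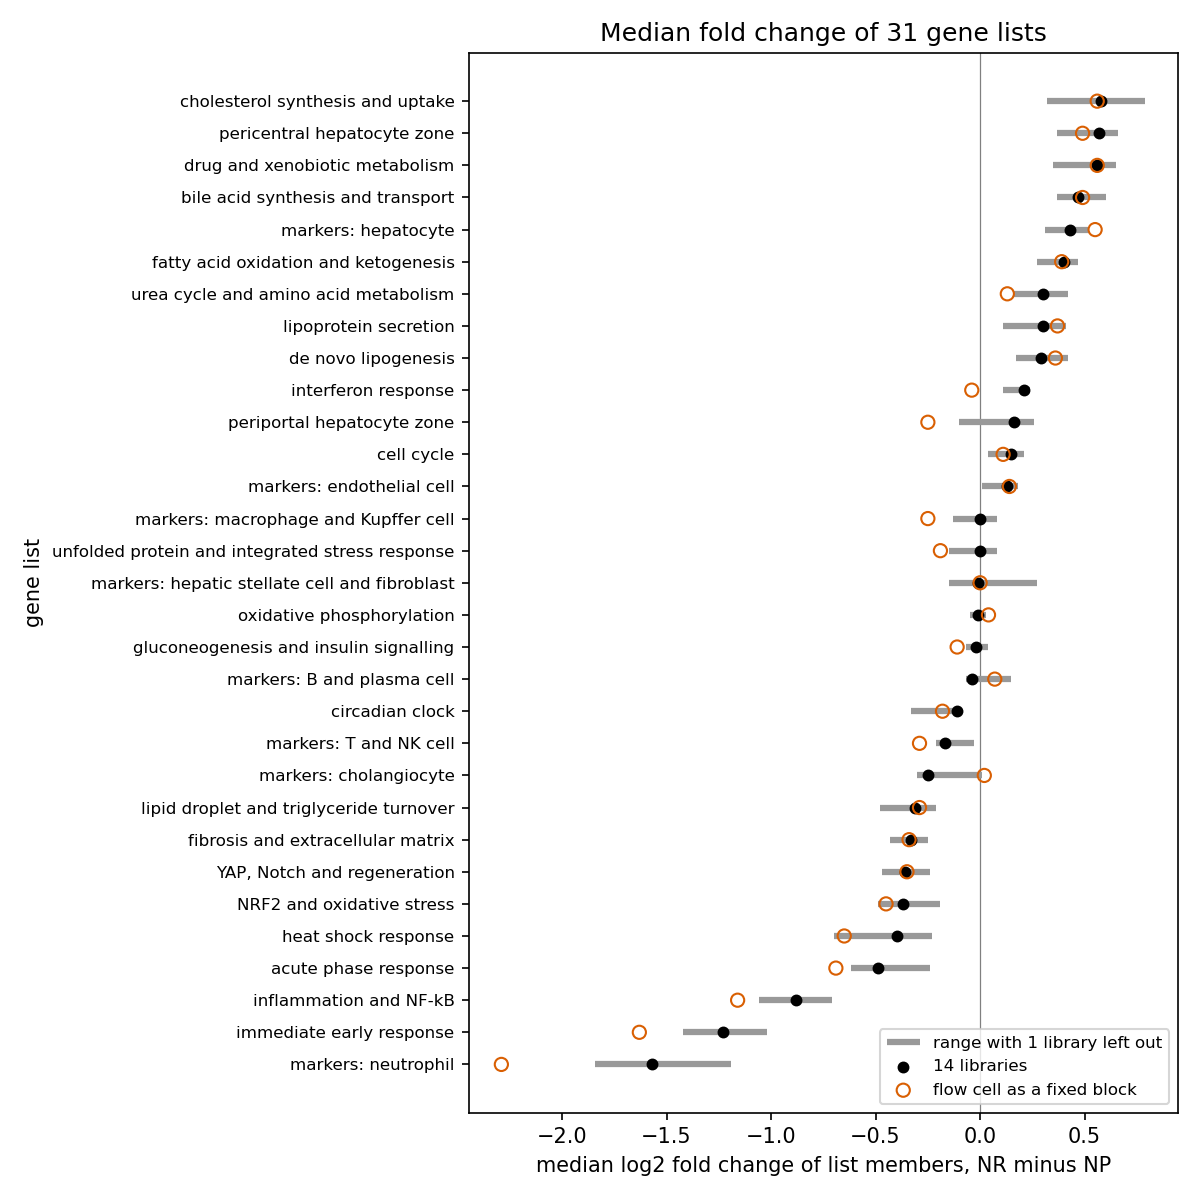
The median log2 fold change (NR minus NP) of the members of each of the 31 tested lists is shown on the horizontal axis, with black points for the 14 libraries, open circles for the fit with flow cell as a block and grey lines for the range with 1 library left out. The neutrophil, immediate early and NF-kB lists lie farthest below 0, at -1.57, -1.23 and -0.88.

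Markers of the other cell types did not follow the neutrophil markers. The median log2 differences were 0.13 for endothelial cells (23 members tested), -0.01 for stellate cells and fibroblasts (20), -0.25 for cholangiocytes (17), -0.17 for T and NK cells (23), -0.04 for B and plasma cells (13) and 0.00 for macrophages and Kupffer cells (22). The cholangiocyte median was 0.02 with flow cell as a block, 0.03 by the status field and 0.01 without NP replicate 4. Camera called none of these 6 lists in the 14 libraries. Blocked by flow cell, it called the macrophage and the T and NK cell lists lower, with medians of -0.25 and -0.29, and it also called the macrophage list lower by the status field (-0.14) and without NP replicate 1 (-0.08). With an estimated correlation the adjusted p was 0.583 and 0.691 in the blocked fit, and 0.493 and 0.52 for the macrophage list in the other 2. The B and plasma cell test pointed up against a median of -0.04, and the stellate test down against a mean of 0.05. The macrophage list was split: SPI1, ITGAX, TYROBP and SLC11A1 were lower in NR at -0.93, -1.70, -0.83 and -1.83 and passed in edgeR when adjusted over the list alone, while 11 of its members lay above 0, and over all genes tested 0 passed in edgeR and 2 were called lower by DESeq2. Its mean was -0.29 against a median of 0.00. The neutrophil score minus the mean score of the other 6 lists differed between the groups by -1.57 (two-sided exact permutation p = 0.00766).

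Among regulatory elements, the smallest p belonged to an enhancer-type element at 133732180 to 133732810 on chromosome 3 (hg38), inside the annotated span of TF, with 21.1 ± 13.2 CPM in NR (SD, n = 6) and 3.41 ± 1.57 CPM in NP (n = 8), a log2 difference of 2.56 ± 0.45. An enhancer-type element in ANG, the angiogenin gene (chromosome 14, 20691020 to 20691460), differed by 1.80 ± 0.33. A promoter-type element in LINC00844 (chromosome 10, 58999720 to 58999910) differed by 2.75 ± 0.49, and enhancer-type elements in SH3PXD2A and 2705 bp from LOC124900272 by 2.14 ± 0.41 and 3.47 ± 0.62. On the lower side, a pair of promoter-type elements in NFIL3, a clock-linked repressor gene (chromosome 9, starting at 91423640 and 91424340), differed by -1.46 ± 0.32 and -1.47 ± 0.32. Promoter-type elements in RUBCNL, in ATG2A and 121 bp from SLC1A5 differed by -3.03 ± 0.62, -1.88 ± 0.40 and -1.11 ± 0.24.

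edgeR called 0 of 61473 elements, with a smallest adjusted p of 0.153. At an unadjusted p under 0.05 there were 3982 elements higher and 3690 lower, 7672 in all against 3074 expected by chance. DESeq2 called 267 higher and 129 lower, of which 210 and 46 were enhancer-type, and limma voom called 0. Without NR replicate 1 edgeR called 91 higher and 62 lower, without NR replicate 2 it called 4 higher, and without the count filter 30 higher and 3 lower. The count at an unadjusted p under 0.05 was 4915 without NP replicate 6.

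Distal elements, with centres over 1000 bp from the ends of all annotated genes, were shifted upwards in NR relative to proximal elements. The median log2 difference was 0.10 over 31790 distal and -0.08 over 29683 proximal elements. Each library's mean score over distal elements minus that over proximal elements was 0.11 ± 0.12 in NR (SD, n = 6) and -0.08 ± 0.14 in NP (n = 8), a difference of 0.19 (two-sided exact permutation p = 0.011). Among elements at an unadjusted p under 0.01, 932 distal elements were higher and 394 lower in NR, against 333 and 544 proximal elements, an odds ratio of 3.86 (95% interval 3.21 to 4.65, Fisher's exact test across elements, which are not independent). By the authors' types the difference was 0.19 (exact p = 0.0186), at 2000 bp 0.196 (exact p = 0.00533), at 500 bp 0.145 (exact p = 0.0769) and in flow cells 1 and 4 together 0.198 (exact p = 0.0536). It was 0.22 within flow cell 1 and 0.19 within flow cell 4, where the libraries are too few for an exact p under 0.05. With the status field as the group it was 0.13 (exact permutation p = 0.147). The median log2 difference of enhancer-type elements minus that of promoter-type elements was 0.189 between the groups. Splits of the same libraries that ignore the groups reached 0.225 and -0.216, so chance cannot be excluded for this measure of the shift. The share of element counts in enhancer-type elements was 31.6 ± 3.42% in NR and 29.3 ± 2.94% in NP (exact permutation p = 0.2). Distal elements include those inside gene bodies. NP replicate 4, scored -0.354, had the most element counts per 100 gene-body counts (59.85), and NR replicate 5, scored 0.323, the fewest (22.43). NR replicate 4 (41.74) and NP replicate 8 (27.86) did not follow this, with scores of 0.038 and -0.049. Whether this ratio takes part in the shift was not tested.

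**Figure D3:**
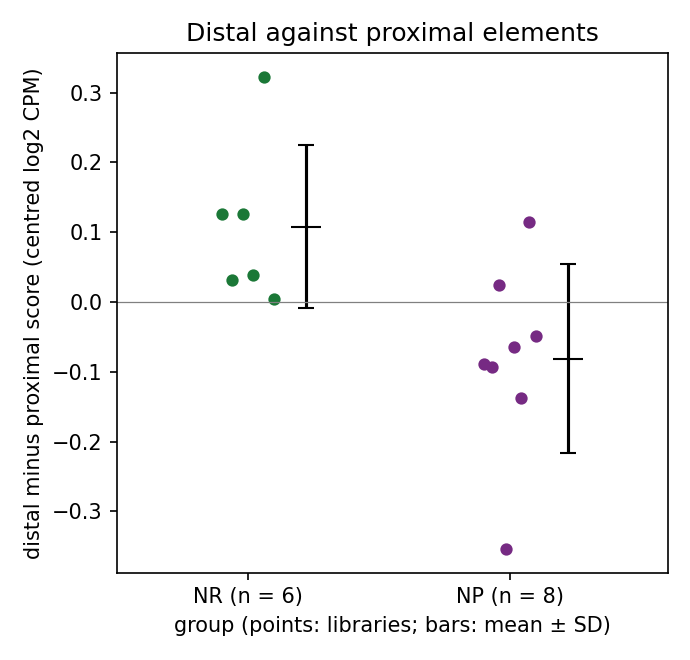
Points give each library's mean centred log2 CPM over distal elements minus that over proximal elements (vertical axis) in NR (n = 6) and NP (n = 8), with bars for the group mean ± SD. All NR values lie at or above 0.004, while 6 of the 8 NP values lie below 0.

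Elements near genes were compared with the genes themselves. Across 14979 genes, the Spearman correlation between a gene's log2 difference and the mean of elements within 100 kb and outside its body was 0.291, across genes, which are not independent. Splits of the same libraries that ignore the groups gave 0.232 on average, and 9 of 100, the real one included, gave a value as large. Elements within 100 kb of the immediate early genes (468 elements) had a median log2 difference of -0.40 and those near neutrophil markers (90) a median of -0.46. Elements near hepatocyte markers (406), pericentral genes (237) and drug metabolism genes (403) had medians of 0.29, 0.32 and 0.24. Camera called these 5 at its preset correlation, each with an adjusted p = 0.388 with an estimated correlation. Elements near the B and plasma cell markers (median -0.24) and the periportal genes (0.13) were also called, with adjusted p = 0.388 and 0.55 with an estimated correlation, while those near NF-kB genes (-0.04) were not called. No gene had 3 or more elements called by edgeR within 100 kb, and at an unadjusted p under 0.01 there were 228 such genes higher and 200 lower. With elements called by DESeq2 there were 32 and 4.

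The spread of the libraries was compared with group and flow cell. The first principal component of log2 CPM over genes held 28.4% of the variance, of which group accounted for 34.9% (permutation p = 0.0232) and flow cell for 17.8% (permutation p = 0.56). In elements it held 20.6%, with 29.2% for group (permutation p = 0.0475) and 16.1% for flow cell (permutation p = 0.602). Without the count filter the share for group was 26.2% over genes (permutation p = 0.0562) and 12.2% over elements (permutation p = 0.223), where the component's Spearman correlation with log10 depth was -0.543 against -0.314 with the filter.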

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

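The tests of depth and of the shallow libraries were set before their values were seen, and those of flow cell, disputed labels, cell share and sample splits after. In 184 comparisons of a group's extreme library with its nearest neighbour, 14 stood apart where 9.2 are expected by chance, and 10 of the 14 were NP replicate 6. Its scores were -0.96 for lipoprotein secretion, -1.24 for drug and xenobiotic metabolism and -1.49 for hepatocyte markers, and its log2 CPM was 5.61 for APOH, 4.47 for GBA3, 4.62 for RNLS and 4.85 for TF, all low, and 6.73 for B3GNT5, 5.37 for GNB2 and 7.26 for TGFB3, all high. NR replicate 4 scored 0.53 for fatty acid oxidation. NP replicate 8, 1 of the 2 shallow libraries, scored 1.05 for stellate cell and fibroblast markers. SNX31 was low in NR replicate 1 (0.94) and NP replicate 5 (-1.46).

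The lower immediate early, NF-kB and neutrophil genes of NR were weighed against depth, disputed labels and flow cell, while resistance itself, blood in the sample and handling of the tissue stay open and untested. Thinning every library to the shallowest left an immediate early median of -1.18 against -1.23, a neutrophil median of -1.28 against -1.57 and an NF-kB median of -0.67 against -0.88. The filter then kept 12385 genes against 16580, so members with low counts can be missing from the thinned medians. Leaving out the 2 disputed libraries gave an immediate early median of -1.34 (exact p of the score 0.0189). For the members that stayed in each fit, neither depth nor the disputed labels are therefore likely to be the whole cause. The status field gave an immediate early median of -0.64 (exact p of the score 0.0879), so the labels leave the size open. With flow cell as a block the immediate early median was -1.63 and the NF-kB median -1.16, but permuting within flow cells gave exact p of 0.0667 and 0.133 over 30 arrangements, so batch and group cannot be told apart for these 2 lists. For neutrophil markers the blocked median was -2.29 and that p 0.0333, the smallest possible, which argues against batch as the whole cause there. This p was not adjusted for the number of lists weighed, and it rests in part on the disputed labels of flow cell 1. Only 2 of 100 splits gave an immediate early median as far from 0 as -1.23 (farthest other -1.53). However, 2 of the 30 arrangements within flow cells gave the blocked fit a median as far as its -1.63 (farthest other -1.70). The exact permutation p adjusted over 31 lists was 0.0994 for the immediate early, neutrophil and NF-kB lists alike, so chance cannot be excluded for any of them.

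The higher hepatocyte lists were weighed in the same way. Thinning left a hepatocyte marker median of 0.41 against 0.43. A lower share of hepatocytes in NP would raise the markers of every other cell type alike. The mean score of the 6 other marker lists differed by -0.05 (exact permutation p = 0.734), and the neutrophil score moved apart from it by -1.57 (exact permutation p = 0.00766). The neutrophil list was set against the others after its values were seen, and more neutrophils would themselves lower the share of hepatocytes. A lower share and more neutrophils in NP therefore stay open. With flow cell as a block the hepatocyte marker median was 0.55, but within flow cells the exact p was 0.167 and flow cell 1, where group labels are disputed, gave -0.11, so batch cannot be told apart here. Camera called 15 lists, and 14 of 100 splits called as many (highest other 19), so chance cannot be excluded for the count of lists.

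edgeR called 0 genes and DESeq2 274. Splits gave DESeq2 as many genes in 7 of 100 cases (highest other 2645), so chance cannot be excluded for that count. Without the 2 shallow libraries DESeq2 called 145, which leaves their part in it open. For elements DESeq2 called 396, and 1 of 40 splits, the real one, gave as many (highest other 129). Splits with 3714 and 4723 genes at an unadjusted p under 0.05, outside those 40, gave 1062 and 5233 elements. Arrangements within flow cells were not run for this count, so chance cannot be excluded for it.

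At an unadjusted p under 0.05, 4 of 100 splits gave as many genes as the 2844 (highest other 4723) and 3 of 100 as many elements as the 7672 (highest other 12668), and at an unadjusted p under 0.01, 3 of 100 as many elements as the 2203 (highest other 5510). Of the 30 arrangements within flow cells in the blocked fit, 8 gave as many genes as its 1663 (highest other 2965), 4 as many elements as its 4770 (highest other 6534) and 4 as many as its 1052 under 0.01 (highest other 1779). The 100 splits ignored flow cell and were not adjusted for the number of results weighed, so chance cannot be excluded for the 3 counts. The correlation of 0.291 between genes and elements within 100 kb was reached in 9 of 100 splits (highest other 0.322), so chance cannot be excluded for it. The split with 4723 genes differed from the groups by exchanging 1 library from each. It called 1582 genes and 2130 elements where the groups called 0, and it followed the first principal component more closely (61.8% of its variance against 34.9%), which points to a structure of the samples besides the groups as labelled. On that component NR replicate 1, whose label is disputed, lay lowest of NR (-23.7) and NP replicate 5 highest of NP (33.7). A wrong label for NR replicate 1 therefore stays open as part of this structure. The count columns of both disputed libraries, however, carry the group of their titles. NP replicate 1, the other disputed library, lay at -28.7, within the range of NP. The CC and CG prefixes of the count columns were not tested against this structure.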

How the results depend on the processing

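Alternatives with unadjusted counts, list permutations or lists with 1 library left out were chosen after the data were seen, as were all for the distal difference except its distances. The 0 genes and 0 elements of edgeR held under the other alternatives run, and causes were not tested unless fewer libraries explain them. DESeq2 called 137 genes higher and 137 lower, and 267 and 129 elements, with 13763 elements at an unadjusted p under 0.05. Libraries thinned to the shallowest gave edgeR 1 gene. The status field gave 5 genes higher and the 12 undisputed libraries 9. No count filter gave 30 and 3 elements, and 15389 unadjusted. This count and the 13763 of DESeq2 come from all elements with at least 1 count. They are not on the scale of the main test, which had 7672 among 61473 filtered elements. Flow cell 1 alone, where group labels are disputed and the lone NR library is assumed to vary like the 2 NP, gave 1 and 2 elements, and 206 genes and 1009 elements unadjusted. With flow cell as a block there were 1663 genes and 4770 elements unadjusted, and with flow cells 1 and 4 blocked 1153 and 4931. With 1 library left out, calls ran from 0 to 23 genes higher and 0 to 8 lower, 0 to 91 and 0 to 62 elements, 1846 to 3717 genes and 4915 to 10296 elements unadjusted, 7 to 9 lists higher and 6 to 8 lower, and a distal difference of 0.146 to 0.222. Of the 8 higher and 7 lower lists, the estimated correlation kept 0 and 0, exact permutation 0 and 0, and fry 0 and 1. The distal difference was 0.145 at 500 bp, 0.127 by the status field, 0.198 in flow cells 1 and 4, and 0.221 and 0.185 in each alone, none past an exact p of 0.05. The group's share of the first component was 26.2% over genes and 12.2% over elements without a filter. Genes with 3 elements numbered 428 at an unadjusted p under 0.01. Flow cell 1 alone, with 1 NR library, reversed 16 of 60 named genes in log2 difference: ACACB -0.33, ACADL -0.40, AKR1D1 -0.17, BAG3 0.17, CPT2 -0.006, CYP1A2 -1.04, GSTA2 -0.73, IL1B 0.31, LATS2 0.045, NR1I2 -0.053, PCOLCE2 -0.054, RHBG -2.56, SLC13A3 -0.14, TGFB3 0.36, TM6SF2 -0.17 and VCAN 0.21. Depth limits the elements: simulated 4-fold changes under 30 counts were recovered in 20.9% of cases.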

Other observations

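The joining of elements into regions and the genes named in uncalled lists were chosen after the data were seen. Elements at an unadjusted p under 0.01 that shared a direction and lay within 20 kb of each other lay together in runs. The run with the most elements, 16 higher in NR, spanned 47.9 kb of chromosome 12 (109115620 to 109163540, hg38) in ACACB, an acetyl-CoA carboxylase gene. It held 18 tested elements in all, and 8 of those at an unadjusted p under 0.01 were enhancer-type. Other runs higher in NR covered SELENOP, the selenoprotein P gene (13 elements), NR1I2 (11), SLC2A2, the hepatic glucose transporter gene (9), CLDN14 (8), ETNK2 (7) and ADCY10 with DCAF6 and MPC2 (7). Runs lower in NR covered SOCS3 (9), NANOS3 with the microRNA host gene MIR23AHG (7) and ZFP36 with PLEKHG2 (7). The genes' own log2 differences were 1.03 for ACACB, 1.37 for NR1I2, 0.99 for SLC2A2 and -2.12 for SOCS3, and none passed in edgeR. A run of 16 was reached in 3 of 100 splits (highest other 22), but splits within flow cells were not run for it. Chance therefore stays open for its number of elements, and elements in a transcribed gene could count reads of the gene itself.

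In lists that camera did not call, several regulators had opposed values. NFIL3 differed by -1.58 ± 0.39 and NR1D1 by -1.19 ± 0.50, while CRY2 and DBP differed by 0.77 ± 0.28 and 0.77 ± 0.35, in a clock list with a median of -0.11. That median was -0.33 without NP replicate 5, -0.31 without NR replicate 1 and -0.10 without NP replicate 7. Interferon genes had a median of 0.21, with IFIT1 at 1.08 ± 0.29 and RSAD2 at 0.91 ± 0.30 against IRF1 at -1.04 ± 0.36. Unfolded protein and integrated stress genes had a median of 0.00, with SESN2 at 0.83 ± 0.23 and PHGDH at 1.05 ± 0.34 against PPP1R15A at -1.12 ± 0.37. The triglyceride list had a median of -0.31, with the acyltransferase genes MOGAT1 at 1.42 ± 0.35 and MOGAT2 at 1.09 ± 0.43 against the lipase gene PNPLA2 at -0.69 ± 0.27. None passed in edgeR over all genes tested. When adjusted over the list alone, 1 clock member lower, 3 stress members higher and 1 lower, 1 triglyceride member higher and 0 interferon members passed. DESeq2 called 1 clock member lower and 1 interferon, 1 stress and 1 triglyceride member higher. Other lists not called by camera had medians of 0.30 (urea cycle and amino acids), -0.37 (NRF2), 0.16 (periportal), 0.15 (cell cycle), -0.02 (gluconeogenesis) and -0.01 (oxidative phosphorylation). The urea cycle list was called higher without the 2 disputed libraries (0.46), by the status field (0.40), without the 2 shallowest libraries (0.33), and without any 1 of NR replicates 1, 3 and 6 and NP replicates 1, 2 and 7, but with an estimated correlation the adjusted p in these was 0.458 to 0.776. Its median was 0.13 with flow cell as a block, -0.68 in flow cell 1, 0.16 without NR replicate 4 and 0.19 without NR replicate 5 or NP replicate 6. The NRF2 list was called lower without the 2 shallowest libraries (-0.39), NR replicate 1 (-0.49) or NP replicate 8 (-0.40), and the interferon list higher without NR replicate 6 (0.23), but with an estimated correlation the adjusted p was 0.576 to 0.632 for NRF2 and 0.665 for interferon. The NRF2 median was -0.19 without NP replicate 6 and -0.03 in flow cell 1, and the interferon median -0.04 with flow cell as a block and -0.32 in flow cell 4. The periportal median turned to -0.25 with flow cell as a block, -0.43 in flow cell 1, -0.21 in flow cell 4 and -0.10 without NR replicate 3. Mean and median differed in sign for gluconeogenesis (mean 0.19) and the periportal list (mean -0.02), and the oxidative phosphorylation test pointed up.

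The 4 livers in neither group had immediate early scores from -0.70 to 1.04 (median 0.00), neutrophil scores from -1.13 to 0.69 (median -0.26) and hepatocyte marker scores from -0.34 to 0.59 (median 0.22), with all 18 libraries normalized together, a scale on which the NR and NP means were -0.72 and 0.54, -0.94 and 0.70, and 0.33 and -0.25.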
